A study of Homo sapiens with 12 samples.

How the data were processed

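BE(2)-C human neuroblastoma cells were transfected with 2 µg of pTRex-GRHL1 or of the empty vector and profiled at 24, 48 and 72 h, in 6 groups of 2 arrays (12 arrays). The cells were kept in DMEM with 10% serum and 1% non-essential amino acids, per the labels. Groups and replicate numbers came from the sample titles. The arrays were 12-sample Illumina BeadChips for total RNA labelled with biotin, per the labels.

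Deposited were a scanner table and a normalized table, both of linear intensity values for 47323 probes. The scanner table also gave a detection p-value for each deposited intensity, per the file headers. Array medians ran from 119.7 to 121 in the normalized table and from 108.2 to 128.7 in the scanner table, and the method of normalization is not given in the sources used here. The deposited detection p-values behaved as 2-sided, since on each array between 3416 and 4076 probes with p under 0.01 were dimmer than the array's background level (97.8 to 116.8 units, the median of probes with p above 0.9). Detection was therefore counted as p under 0.01 together with a signal above that level.

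The sample names in the scanner table conflicted with those in the normalized table for 7 of 12 columns. Each scanner column matched a single normalized column with a rank correlation of at least 0.999974, while the next best match reached at most 0.8757. The bright GRHL1 probe ran against the scanner table's name on 6 arrays and against the normalized table's name on 0. The normalized table with its own names was used throughout, a choice made after the GRHL1 probe was seen, and the scanner table served to count on how many arrays a probe was detected, to compare the 2 tables and for 1 alternative. The detection limit on the normalized scale was 128.3 units, the level read off at the rank below which 95% of undetected probes lay.

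The analysis plan had named limma's neqc, which takes detection p-values as 1-sided and so could not be used. In its place the normalized intensity was background-corrected with the normexp model of limma (offset 16) and put on the log2 scale, without a further quantile step, and 1 missing value took the median of its probe. Log2 differences are on that offset scale and understate changes of dim genes. Probe names came from the platform annotation, which gave 1 gene for 30113 probes, several for 8 and none for 17202. Entrez identifiers of 30074 probes were found in a RefSeq gene table of assembly GRCh38.p14, used for symbols only, and 0 symbols changed. Probes detected on at least 2 of 12 arrays and naming 1 gene were kept (16501), and the probe with the highest mean stood for its gene, leaving 12323 genes.

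Differences were tested with limma (lmFit with a mean for each of the 6 groups, eBayes with 6 residual and 3.72 prior degrees of freedom) and Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The comparisons were GRHL1 plasmid against empty vector at each time and averaged over the 3 times, the change of that difference with time (an F test), and 48 h and 72 h against 24 h in empty vector cells. SE is limma's moderated standard error. Where all arrays of a group lay below the limit, the fold is a bound of the other group's normalized intensity over the limit, from means of log2 values and without background subtraction. No fold is given where both groups lay below the limit. The genes named were fixed by rule before the data were examined: GRHL1, MYCN and HDAC3, the 12 largest rises and 12 largest falls of the mean comparison among called genes with the same sign at all 3 times, the 5 largest in each direction for the other comparisons, the 6 smallest p for the change with time, and in each gene list up to 4 called members, or the 2 with the smallest p, as values only, where fewer than 2 were called. Not every gene that the rule allows is printed.

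Before the data were examined 27 gene lists were also fixed (808 entries, of which 756 were on the array and 599 were tested). They were tested with limma's camera at its preset correlation of 0.01, and again with an estimated correlation and with fry. Genes of a list that are not on the array are not analysed here. Tests were run in R 4.3.3 with limma 3.58.1, and tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

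The analysis was tested on simulated data for all 12323 genes with 200 changed. In the mean comparison it recovered 87% of changes of 0.5 and 100% of changes of 1 on the log2 scale, with 16 of 203 calls false. At 24 h it recovered 19% and 87%, at 48 h 19% and 83% and at 72 h 18% and 83%. The simulated changes were the same at each time, so recovery of changes that vary with time was not tested. Rises and falls, and bright and dim genes, were not counted apart. The percentages therefore do not show how well falls of genes near the detection limit are recovered.

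Alternatives covered the background correction, offset, scaling, detection filter, probe choice, replicate blocks, array weights, variance trend, threshold, the samples in the fit and the removal of each array. The series text speaks of paired empty vector and GRHL1 samples but does not say what a replicate number marks, so the comparisons were fitted without pairs, as planned before the data were examined, and with pairs as an alternative. The 2 arrays per group limit the precision of each comparison. The slide as a block could not be run because the files used here name no slide.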

Results

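The series profiled mRNA in BE(2)-C cells, a human neuroblastoma line, after transfection with a plasmid carrying GRHL1 (pTRex-GRHL1) or with the matching empty vector (pTRex-Dest30). GRHL1 encodes a grainyhead-like transcription factor best known from epithelia, and the series title names it together with MYCN, the amplified oncogene of many neuroblastomas, and the histone deacetylase HDAC3. Total RNA was taken 24, 48 and 72 h after transfection with 2 µg of plasmid. Biotin-labelled cRNA was hybridised to Illumina BeadChips, with 2 arrays for each plasmid at each time, 12 arrays in 6 groups. The arrays detected between 17950 and 19427 of 47323 probes, and 12323 genes were tested. The number of arrays limits the precision, and the labels do not say whether the replicates of a group were separate cultures, so p-values measure only the spread between these samples. Replicates of a group correlated with r between 0.9917 and 0.9925 across genes. On the first principal component (20.4% of the variance) the empty vector arrays lay between -12.25 and -6.5 and the GRHL1 arrays between 7.47 and 11.88. On the second (14.6%) the 24 h arrays lay between 6.21 and 15.12 and the later arrays between -8.04 and -1.44.

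The transfected gene was examined first. Probe ILMN_1651286 of GRHL1 read 11037 ± 2725 intensity units (SD, n = 2) at 24 h in GRHL1-transfected cells, 5447 ± 1100 (n = 2) at 48 h and 5713 ± 361 (n = 2) at 72 h. In empty vector cells the same probe stayed below the detection limit of 128.3 on all 6 arrays, with means of 110.4, 103.4 and 103.6. Against that limit GRHL1 was at least 84.7-fold, 42.0-fold and 44.5-fold higher at 24, 48 and 72 h (limma adjusted p = 6.93e-06, 9.72e-06 and 9.6e-06). At 48 and 72 h the scanner table's sample names would turn the log2 difference to -3.94 and -3.55. The normalized names were preferred after this same probe was seen, so its rise at 48 and 72 h is no separate support. At 24 h both tables carry the same names. Probes ILMN_1769934 and ILMN_1795767 of GRHL1 stayed near background, at group means of 120.8 to 127.9 and 96.9 to 113.7, and each was detected on 1 of 12 arrays. Where these probes lie relative to the plasmid insert is not given in the sources used here. The brightest MYCN probe had group means between 24273 and 25773 and lay at 89.1% to 100% of the highest value of its array, so its log2 difference over the 3 times (-0.01 ± 0.05 SE, 6 arrays against 6, adjusted p = 0.975) is read near the top of the scale and may hide a change. MYCN probe ILMN_1653761, at 26.9% to 34.7% of that value, gave -0.10 ± 0.06 (adjusted p = 0.566 over 22986 probes), and at each of the 3 times both GRHL1 arrays read below both empty vector arrays. HDAC3 read 1041 in GRHL1 cells and 1062 in empty vector cells, with a log2 difference of -0.03 ± 0.06 (adjusted p = 0.911).

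**Figure D1:**
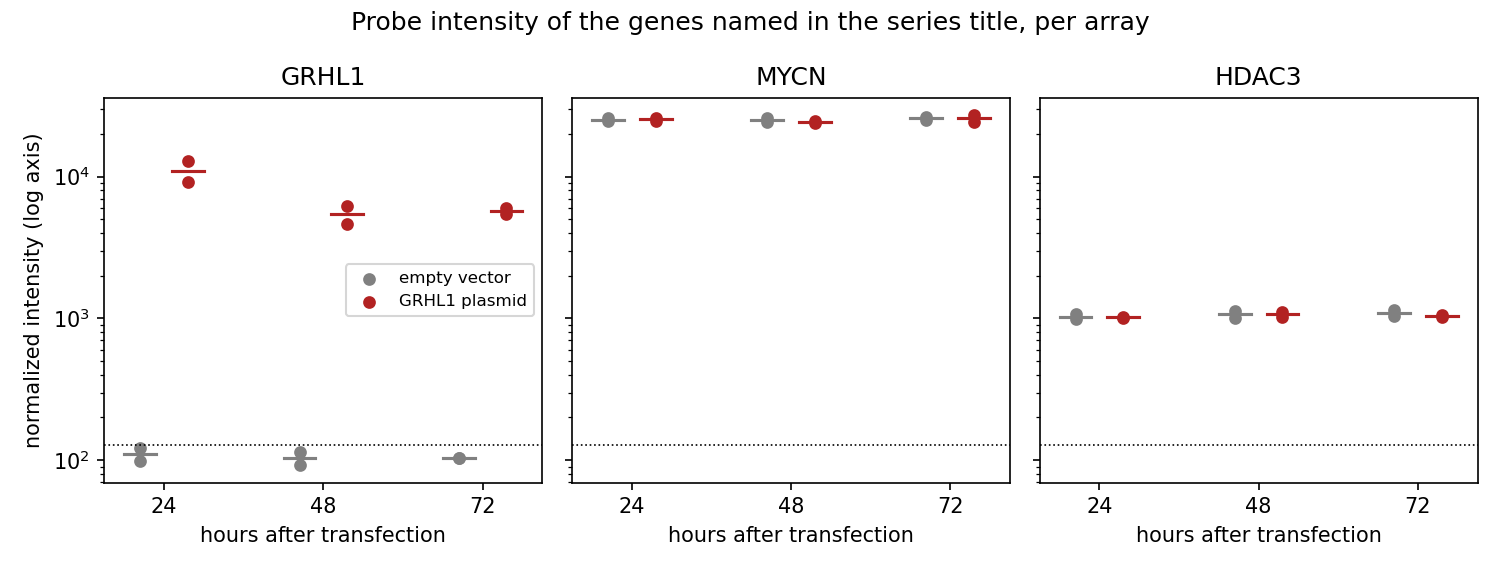
Normalized intensity (log axis) of the brightest probe of GRHL1, MYCN and HDAC3 on each of 12 arrays against hours after transfection, with a short line at each group mean and a dotted line at the detection limit of 128.3. Under the normalized table's names the 6 GRHL1 plasmid arrays lie between 4669 and 12964 for GRHL1 and the 6 empty vector arrays between 92.3 and 122.8.

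Averaged over the 3 times, 189 genes rose and 22 fell with the GRHL1 plasmid (211 of 12323 genes, limma with Benjamini-Hochberg adjustment). Apart from GRHL1 itself, the largest rises among genes measured on some or all arrays of both transfections were in AIF1L, an actin-binding protein related to allograft inflammatory factor 1 (log2 difference 2.64 ± 0.07 SE, adjusted p = 3.44e-08), SOWAHA (2.11 ± 0.17, adjusted p = 0.000174), the choline transporter-like gene SLC44A2 (2.01 ± 0.07, adjusted p = 3.6e-07) and MGP, which encodes the calcification inhibitor matrix Gla protein (1.92 ± 0.13, adjusted p = 4.55e-05). RHBDF1, an inactive rhomboid, rose at least 2.51-fold, RGCC, a regulator of the cell cycle, at least 1.91-fold, the aldehyde dehydrogenase ALDH3B2 at least 1.78-fold and the calcium-binding gene EFHD1 at least 1.57-fold in normalized intensity, bounds because these 4 were below the detection limit on every empty vector array. TMEM54 (1.83 ± 0.21), NDRG1 (1.59 ± 0.15) and the surface glycoprotein gene CD24 (1.59 ± 0.08) also rose. TMEM54 was above the limit on 1 of 6 empty vector arrays and NDRG1 on 5 of 6. A second probe of AIF1L gave a smaller log2 difference of 1.5 than the 2.64 at the main one. That of ALDH3B2 gave 1.06, where 2.41 was fitted at the main probe. The fitted value is read against background, so the ALDH3B2 probes cannot be ranked.

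The falls were smaller. The deepest was in AMHR2, the receptor of anti-Müllerian hormone (-0.70 ± 0.07, adjusted p = 0.00054), and MLC1 fell by 0.58, the pro-apoptotic BH3-only gene HRK by 0.54, the protocadherin gene PCDH10 by 0.46 and GLDC, of the glycine cleavage system, by 0.44 on the log2 scale. PCDH10 read -0.21, -0.97 and -0.20 at 24, 48 and 72 h, and its second probe gave -0.04 over the 3 times, while that of MLC1 gave -0.26. MINAR2 and RIIAD1 fell by 0.42 each, the neurofilament gene NEFM by 0.38, the contactin gene CNTN1 by 0.37, and the chemokine gene CX3CL1 and CCDC137 by 0.36 each. CXADRP3 was below the limit on all 6 GRHL1 arrays and at least 1.06-fold lower there. In GRHL1 cells MLC1, HRK and MINAR2 were above the limit on 1, 2 and 1 of 6 arrays.

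Of the 189 genes that rose, 188 had a positive difference at all 3 times, and all 22 genes that fell had a negative one. The calls were made on the mean of these same 3 differences, which favours a shared sign, so the counts are not separate support. The median log2 difference was 0.52 for the genes that rose and -0.35 for those that fell, with genes below the limit in a group set at their bound, and 20 rose at least 2-fold by these values. From these values 3 rises without a usable bound were left out. Of the 189 genes that rose, 28 were below the limit on all empty vector arrays, against 263 of the 12323 genes tested. Such genes pass the detection filter more easily if GRHL1 arrays read higher, so the filter itself favours rises among them. The median difference over all genes was -0.008, and 1505 genes had an unadjusted p under 0.05 where 616 would by chance, 802 higher and 703 lower. Fitting only the 4280 genes with an empty vector mean of at least 4 times the limit gave 79 rises and 44 falls. Other settings gave fewer falls, with 104 rises and 5 falls without a detection filter and 169 and 10 with all probes, named or not. The number of falls thus depends strongly on the setting. With a variance trend and robust limma estimates 299 rose and 93 fell, and leaving out single arrays left 128 to 185 calls. With the same-numbered arrays of a time taken as pairs 143 genes were called, 14 of them lower. Of these calls 128 were shared with the main fit, so the number of calls also depends on pairing.

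**Figure D2:**
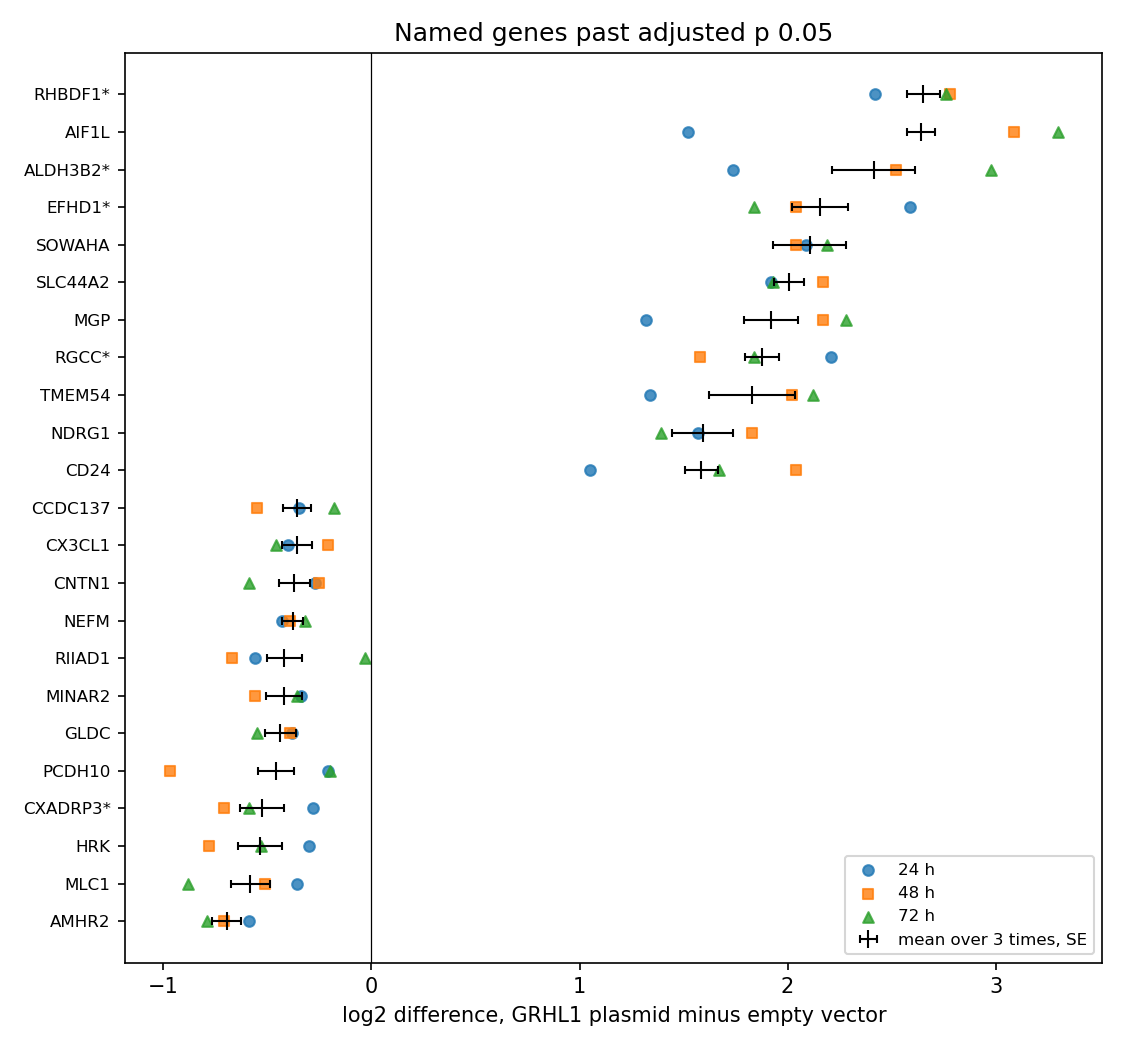
Log2 difference between GRHL1 plasmid and empty vector for the named genes other than GRHL1, at 24 h (circles), 48 h (squares) and 72 h (triangles), with the mean over the 3 times and its SE in black. An asterisk marks genes below the detection limit on all arrays of a group, whose plotted value is the fitted one and not a bound. The 11 genes that rose lie between 1.05 and 3.3 at every time, and the 12 that fell stay below 0. The rule that chose these genes required the same sign at all 3 times.

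Genes of epithelial junctions were among those that rose. In the list of grainyhead family and epithelial junction genes, 3 of 11 tested members (30 given) rose and 0 fell, the same as adjusted over the list alone. Over all genes 189 of 12323 rose. The 3 members were CGN, the tight junction protein cingulin (0.84 ± 0.09, adjusted p = 0.00119), the epithelial repressor OVOL2 (at least 1.07-fold, adjusted p = 0.000256) and the epithelial GTPase RAB25 (at least 1.16-fold, adjusted p = 0.0199). OVOL2 and RAB25 were below the limit on all empty vector arrays. The detection filter counts arrays of both transfections, so a member dim in empty vector cells is kept more easily if GRHL1 arrays read higher. Members dim in both may thus be missing from the number tested. In the desmosome, keratin and cornified envelope list 2 of 13 tested members (30 given) rose and 0 fell (3 and 0 adjusted over the list alone). They were JUP, or plakoglobin (0.99 ± 0.07, adjusted p = 4.79e-05), and PKP1 (at least 1.01-fold, adjusted p = 0.0447). The value of JUP depends on the probe, with 0.47 and 0.38 from its 2 other probes. Among Schwann and glial markers, of which 3 were tested, ERBB3 rose (0.84 ± 0.08, adjusted p = 0.000438), and it was above the limit on 2 of 6 empty vector arrays, with 0.45 from a second probe. None of 5 keratinocyte and carcinoma epithelial markers passed the test, with KRT19 at -0.14 ± 0.09 (adjusted p = 0.558).

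The calls among neuronal genes were falls. Of 27 neuronal differentiation genes 0 rose and 2 fell, NEFM and CNTN1 (1 and 5 adjusted over the list alone), and 9 of 27 differences were above 0. The adrenergic and catecholamine list had 1 fall in 20 members, the vesicular monoamine transporter SLC18A1 (-0.35 ± 0.07, adjusted p = 0.0397, -0.20 from a second probe, and 1 adjusted over the list alone). In the MYC and MYCN target list 1 of 34 members fell, the RNA polymerase I subunit POLR1B (-0.31 ± 0.06, adjusted p = 0.0298, and 1 adjusted over the list alone), while PTMA read 0.20 ± 0.07 (adjusted p = 0.221). Among 30 hypoxia and glycolysis genes NDRG1, ADM (0.72 ± 0.12, adjusted p = 0.0176) and BNIP3L (0.34 ± 0.06, adjusted p = 0.0125) rose and 0 fell, as adjusted over the list alone. Single calls were the small heat shock gene HSPB1 (0.45 ± 0.06, adjusted p = 0.00271) in 18 heat shock genes, CDH11 (1.09 ± 0.19, adjusted p = 0.0193) in 16 mesenchymal-type genes, the laminin gene LAMB2 (at least 1.04-fold, adjusted p = 0.0447) in 26 matrix and adhesion genes, HRK in 20 apoptosis regulators, and S100A4 (-0.31 ± 0.06, adjusted p = 0.0238) in 10 fibroblast markers.

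No list as a whole passed limma's camera test against the other genes in the mean comparison, and 15 of 27 held no called member. The lowest camera adjusted p, 0.0555, was shared by the desmosome list (higher), the MYC and MYCN targets (lower), the neuronal list (lower) and the Schwann and glial markers (higher). With an estimated correlation these gave adjusted p = 0.336, 0.336, 0.375 and 0.336. The one-way fry test, which asks whether a list moves and not whether it differs from other genes, put 5 lists past the threshold, the same 4 and the epithelial junction list. Camera adjusted p was 0.104 for epithelial junction genes, 0.143 for cholesterol biosynthesis, TGF-beta response genes and fibroblast markers, 0.183 for G1/S and mitochondrial respiratory chain genes, and 0.4 for apoptosis regulators. It was 0.524 for the adrenergic, G2/M, heat shock and hypoxia lists, 0.584 for cell cycle inhibitors and p53 targets, 0.599 for keratinocyte markers and ribosomal protein genes, 0.613 for immediate early genes and 0.659 for unfolded protein response and ATF4 target genes. It was 0.738 for histone deacetylases, leukocyte markers and NF-kB genes, 0.78 for mesenchymal-type genes, 0.781 for interferon-stimulated genes, 0.909 for histone genes and 0.979 for matrix genes. Median, mean and test did not share a sign in 6 lists (matrix, heat shock, histone deacetylase, hypoxia, mesenchymal-type and unfolded protein response).

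At 24 h 47 genes rose and 0 fell. The count rests on each array of that time, with 17 and 24 calls without replicate 1 or 2 of empty vector, 11 and 10 without replicate 1 or 2 of GRHL1, 10 from the 4 arrays alone and 19 with the same-numbered arrays of a time taken as pairs. Besides GRHL1 the largest rises by fitted log2 difference were EFHD1 (at least 1.71-fold, adjusted p = 0.00131), RHBDF1 (at least 2.38-fold, adjusted p = 7.12e-05), RGCC (at least 2.42-fold, adjusted p = 0.000101) and SOWAHA (log2 difference 2.09 ± 0.30, adjusted p = 0.0221), each from 2 arrays against 2. For the genes given as bounds the fitted value is read against background, and the bounds do not show that they rank first. JUP (1.02 ± 0.12, adjusted p = 0.00592, with 0.37 and 0.10 from its other probes) rose in the desmosome list (1 of 13, and 2 adjusted over the list alone) and CGN (1.05 ± 0.16, adjusted p = 0.0291) in the epithelial junction list (1 of 11, and 3 adjusted over the list alone). Both lists lay higher and the MYC and MYCN targets lower than other genes (camera adjusted p = 0.0426 each), the last with 0 of 34 members called. None of the 3 held with an estimated correlation (adjusted p = 0.282 for each). With the replicate number as a fixed block camera gave adjusted p = 0.0756 for the desmosome list, 0.0767 for the junction list and 0.0756 for the MYC and MYCN targets. A total of 1079 genes had an unadjusted p under 0.05, of which 305 were lower.

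At 48 h 50 genes rose and 5 fell, and there were 19 and 28 calls without replicate 1 or 2 of empty vector and 21 from the 4 arrays alone, each with 0 falls. Without replicate 1 or 2 of GRHL1 there were 28 and 27 calls with 3 and 4 falls, and with pairs 33 with 1 fall. AIF1L rose by 3.09 ± 0.12 (adjusted p = 2.87e-06), SLC44A2 by 2.17 ± 0.12 (adjusted p = 3.2e-05), RHBDF1 at least 2.96-fold (adjusted p = 1.25e-05) and ALDH3B2 at least 2.09-fold (adjusted p = 0.0119). The falls were PCDH10 (-0.97 ± 0.15, adjusted p = 0.0229), AMHR2 (-0.71 ± 0.12, adjusted p = 0.0388), CLDND2 (-0.60 ± 0.10, adjusted p = 0.0454), CA10 (-0.60 ± 0.10, adjusted p = 0.0464) and the cyclin-dependent kinase inhibitor gene CDKN2B (at least 1.09-fold lower, adjusted p = 0.00591). CA10 was above the limit on 1 of 2 GRHL1 arrays, and second probes of PCDH10 and CDKN2B read -0.12 and 0.12. Of genes with an unadjusted p under 0.05, 491 were higher and 530 lower. No list passed camera, with the lowest adjusted p at 0.0898 for cholesterol biosynthesis genes and for Schwann and glial markers.

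At 72 h 38 genes rose and 2 fell, and there were 22 calls without either empty vector array, 18 without replicate 1 of GRHL1, and 12 from the 4 arrays alone, each with 0 falls. AIF1L rose by 3.30 ± 0.12 (adjusted p = 1.51e-06), MGP by 2.28 ± 0.22 (adjusted p = 0.00186), ALDH3B2 at least 2.39-fold (adjusted p = 0.00464) and RHBDF1 at least 2.24-fold (adjusted p = 1.37e-05). With the same-numbered arrays taken as pairs 29 genes were called, 27 higher and 2 lower. Of genes with an unadjusted p under 0.05, 467 were higher and 451 lower. AMHR2 fell (-0.79 ± 0.12, adjusted p = 0.0283) and TCF24 was at least 1.3-fold lower (adjusted p = 0.0404). Neuronal differentiation genes lay lower than other genes (camera adjusted p = 0.00957, and adjusted p = 0.663 with an estimated correlation), with 0 of 27 members called and 3 lower adjusted over the list alone. GAP43, the growth cone protein, had the smallest p of the list (-0.63 ± 0.12, adjusted p = 0.102).

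The times shared many called genes. The 24 and 48 h comparisons had 29 rises in common where 0.19 would be shared by unrelated lists, the 24 and 72 h comparisons 18 (0.14) and the 48 and 72 h comparisons 29 (0.15), and 17 genes were called at all 3 times. No array was used at more than 1 time, but all 3 comparisons took the spread of each gene from the same 12 arrays. A gene with a small estimated spread is thus more easily called at every time. The values for unrelated lists are therefore too low as a measure of overlap without an effect. Across all 12323 genes, which are not independent replicates, the log2 differences correlated with Pearson's r = 0.375 for 24 and 48 h, 0.358 for 24 and 72 h and 0.424 for 48 and 72 h, and with Spearman's rho = 0.165, 0.169 and 0.217. Without GRHL1 the Pearson values were 0.314, 0.292 and 0.37. A test of change in the GRHL1 difference with time called 1 gene, AIF1L (limma adjusted p = 0.0229), at 1.52 ± 0.12, 3.09 ± 0.12 and 3.30 ± 0.12 for 24, 48 and 72 h, and 664 genes had an unadjusted p under 0.05. Next by p were CDKN2B, KNDC1, ENTREP2, GSTM1 and OR2A1 (adjusted p = 0.52 each), of which GSTM1 read 0.36, 1.21 and 1.21. The AIF1L call was lost when any of 11 of the 12 arrays was left out, and 0 genes were called with the same-numbered arrays of a time taken as pairs.

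In empty vector cells, which show the time course without the GRHL1 insert, cholesterol biosynthesis genes lay lower at 48 h than at 24 h. The median log2 change of the 19 tested members was -0.59, 2 were above 0 and 14 fell adjusted over the list alone, while 0 passed over all genes. The mevalonate pathway gene MVD read -0.97 ± 0.13 (adjusted p = 0.0653) and DHCR7, of the last step of cholesterol synthesis, -0.78 ± 0.11 (adjusted p = 0.0724). The camera adjusted p was 4.57e-19, and adjusted p = 0.042 with an estimated correlation. Immediate early genes also lay lower (median -0.26, 24 members, 3 lower adjusted over the list alone, camera adjusted p = 9.17e-07, adjusted p = 0.042 with an estimated correlation), with KLF6 at -0.60 ± 0.10 (adjusted p = 0.105). G2/M and mitosis genes lay higher (median 0.13, 37 of 44 above 0, 0 called over all genes or adjusted over the list alone, camera adjusted p = 0.000169, adjusted p = 0.042 with an estimated correlation), with CENPF at 0.42 ± 0.10 (adjusted p = 0.238). The lower unfolded protein response and ATF4 targets (median -0.16, camera adjusted p = 1.12e-06, 3 lower adjusted over the list alone) and the higher keratinocyte markers (camera adjusted p = 0.0207, 1 of 5 higher adjusted over the list alone) did not hold with an estimated correlation (adjusted p = 0.211 and 0.173). Over all genes ATP9A, a phospholipid flippase, was the single call (0.99 ± 0.10, adjusted p = 0.0185), and 1234 genes had an unadjusted p under 0.05.

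At 72 h against 24 h in empty vector cells 6 genes rose and 1 fell. They included the complement gene C7 (1.32 ± 0.16), the tetraspanin gene TSPAN8 (1.25 ± 0.15), IGFBP5 (0.99 ± 0.13), RIMBP2 (0.78 ± 0.10) and HAMP (at least 1.29-fold), and the quinone oxidoreductase gene NQO1 fell (-0.90 ± 0.11), all at adjusted p = 0.048. The cholesterol list (median -0.29, 6 of 19 lower adjusted over the list alone, camera adjusted p = 1.85e-09) and the immediate early list (median -0.21, 5 of 24 lower adjusted over the list alone, camera adjusted p = 4.92e-06) again lay lower, and G2/M genes higher (median 0.13, camera adjusted p = 0.00463). With an estimated correlation these lists had adjusted p = 0.196, 0.104 and 0.104. The camera adjusted p of the G2/M list was 0.176 without replicate 2 at 24 h and 0.0564 without replicate 2 at 72 h. The unfolded protein response and ATF4 list (median -0.08, camera adjusted p = 0.0229) had adjusted p = 0.691 with an estimated correlation. All 7 gene calls had adjusted p just under the threshold, and leaving out any array left 0 to 3.

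**Figure D3:**
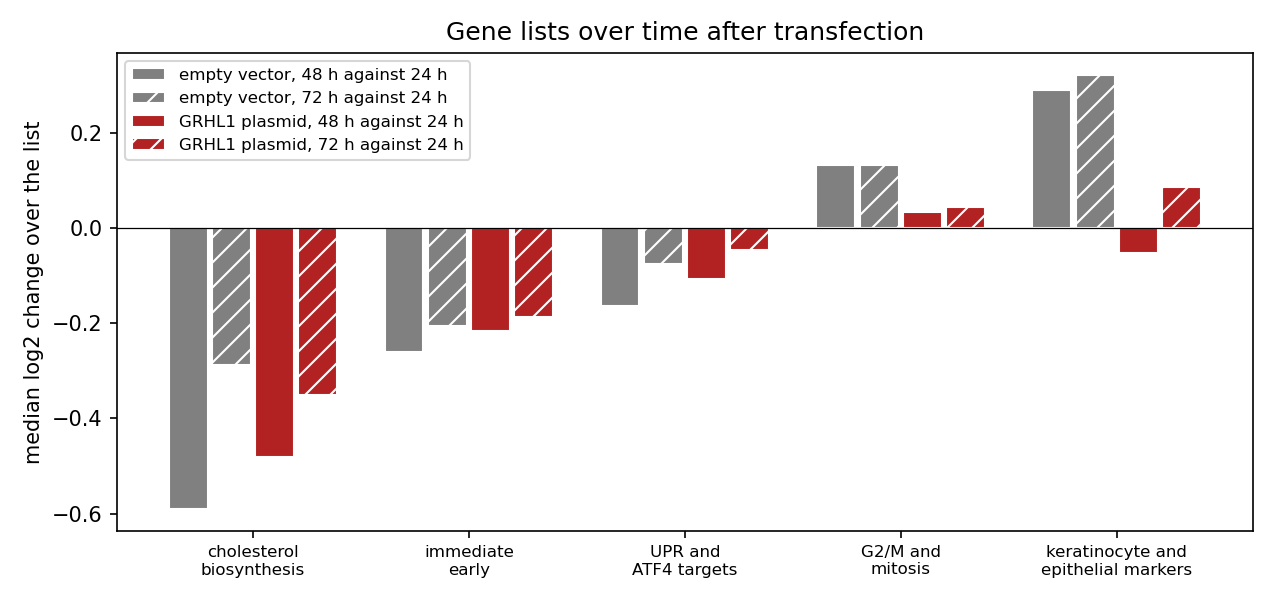
Median log2 change from 24 h over the members of 5 gene lists, in empty vector arrays (grey) and GRHL1 plasmid arrays (red), at 48 h (plain bars) and 72 h (hatched bars). The cholesterol list reads -0.59 and -0.29 in empty vector cells and -0.48 and -0.35 in GRHL1 plasmid cells, a comparison that was added after the empty vector values were seen.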

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

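The tests of between-array normalization and of a single faulty AIF1L probe, the fit of bright genes alone and the cholesterol list in GRHL1 plasmid arrays were chosen only after the result was seen.

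More genes rose than fell with the GRHL1 plasmid (189 and 22, limma, against 802 and 703 at an unadjusted p under 0.05). The real split was set among 100 splits of the 4 arrays of each time into 2 and 2, the others drawn at random. Of the 100, only the real one called as many as 211 genes, and the highest other called 14. This argues against chance for the number of calls. A split that exchanges arrays also puts the plasmid difference into the spread, which lowers its count. The count takes both directions together, so it cannot test chance for the imbalance of rises and falls. A detection floor that hides falls of dim genes was examined in genes with an empty vector mean of at least 4 times the detection limit. Among called genes of this kind 80.9% rose (38 of 47, exact 95% interval 66.7 to 90.9). When these 4280 bright genes were fitted alone the share was 64.2% (79 of 123, interval 55.1 to 72.7). Over all genes it was 89.6%, so part of the imbalance may come from dim genes. The intervals take genes as independent, which genes read on the same arrays are not. They therefore do not measure the spread between replicates. More rises than falls were called among bright genes too, but these counts cannot decide whether a floor is the whole cause. With equal array medians 90.4% rose, but this changed almost no call, so a shift by the authors' normalization stays open, as does an untested effect of GRHL1 itself.

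The test of change with time called AIF1L (adjusted p = 0.0229), which is why it is weighed here, and that call was lost when any of 11 of 12 arrays was left out and with pairs within each time. The difference grew by 1.78 on the log2 scale between 24 and 72 h (95% interval 1.39 to 2.18). A second, dimmer AIF1L probe grew by 1.44 (0.75 to 2.14), which argues against a single faulty probe. The other 187 genes that rose had a median change of -0.063 (quartiles -0.25 and 0.16), so growth of this size was not common to them as a set, although single genes such as GSTM4 (-0.02 at 24 h and 1.18 at 72 h) also read higher later. A slow response of AIF1L to GRHL1 may be a hypothesis for a further series, and it was not tested here.

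Cholesterol biosynthesis genes lay lower at 48 h than at 24 h in empty vector cells (median -0.59). The GRHL1 plasmid arrays, which share no array with these, gave a median of -0.482 (17 of 19 members below 0, camera adjusted p = 9.93e-14, and adjusted p = 0.185 with an estimated correlation). This argues against a feature of the empty vector arrays at 24 h alone. If the arrays of a time had a technical or culture difference in common, for example in the day of harvest or the age of the medium, it could not be separated from time. The cause of the lower values was not tested.

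The scanner table gave signals outside the comparisons. Under its own sample names the bright GRHL1 probe read 4523.5 on replicate 2 of empty vector at 48 h, and 5118.5 and 5722.5 on replicates 1 and 2 at 72 h, far above the background of an empty vector array. The ranks of these columns match GRHL1 plasmid columns of the normalized table, so the names over the scanner columns are a candidate source of error, and with them limma called 0 genes in the mean comparison (479 at an unadjusted p under 0.05). Nothing but the values says which table carries the right names, and the deciding probe is that of the transfected gene. That probe tells the transfection but not the time. It read 5893.2 in the scanner column headed replicate 2 of GRHL1 at 72 h, whose ranks match replicate 1 of GRHL1 at 48 h. The calls and list results that use arrays of 48 or 72 h, also through the shared spread, rest on the choice of the normalized names. The 4 arrays of 24 h have the same names in both tables, and these alone gave 10 calls at 24 h. Among 6485 probes with no gene name, 13 were higher and 5 lower in the mean comparison of 22986 probes, and what they measure was not analysed here.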

How the results depend on the processing

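The tests with a second quantile step, with the scanner table's names, with bright genes alone and of the correlations without each array were chosen only after the result was seen. Counts below are genes called by limma for the mean, 24 h, 48 h, 72 h, change with time, and empty vector 48 h and 72 h against 24 h, which were 211, 47, 55, 40, 1, 1 and 7. With no background correction and a further quantile step they were 380, 106, 122, 88, 7, 44 and 60, with the authors' values on the log2 scale 345, 102, 109, 83, 2, 35 and 40 (204 of the 211 shared in each), and with a variance trend and robust estimates 392, 123, 124, 97, 4, 56 and 74 (198 shared). Without a detection filter they were 109, 16, 34, 22, 0, 0 and 0. Adjusted p under 0.1 gave 323, 86, 85 and 65 for the first 4 and 11 for empty vector at 48 h. A log2 difference of at least 1 gave 30, 25, 32 and 25, with 0 and 2 for empty vector. Offset 50 gave 85, 86 and 66 at the single times and 20 and 12 for empty vector, and fits of the 4 arrays of a time alone gave 10, 21 and 12. Bright genes alone gave 123 in the mean comparison. For empty vector at 48 h and 72 h, probes detected on all 12 arrays gave 26 and 24, equal array medians and a second quantile step 5 and 0 each, all probes 0 and 0, and the 6 empty vector arrays alone 0 and 0. The mean of a gene's probes gave 3 at 48 h, and detection p under 0.05 and array weights gave 0 each at 72 h. The change with time gave 0 calls with the mean of a gene's probes and with all probes. The scanner table under its own names gave 0 for all 7 counts and turned GRHL1 to -3.94 at 48 h and -3.55 at 72 h.

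Correlations of the differences (24 with 48 h, 24 with 72 h, 48 with 72 h) were 0.456, 0.443 and 0.512 with the authors' values and 0.314, 0.292 and 0.37 without GRHL1, and the last was 0.462 with probes detected on all arrays. Gene lists past the threshold were 0, 3, 0, 1, 5 and 4 (mean, 24, 48, 72 h, empty vector 48 and 72 h). An estimated correlation gave 0 at 24 h, 0 at 72 h, and 3 and 0 for empty vector. Fry one way gave 5 in the mean, 1 at 24 h, 0 at 72 h and 1 for empty vector at 72 h, and fry either way 21, 10, 12, 7, 13 and 18.

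Leaving out 1 array at a time leaves a group with 1 sample, which is assumed to vary like the other groups. The ranges were 128 to 185, 10 to 43, 19 to 56, 18 to 42, 0 to 1, 0 to 1 and 0 to 3, and for the correlations 0.303 to 0.375, 0.304 to 0.358 and 0.36 to 0.424. The mean count fell to 139 without GRHL1 24 h replicate 1, 130 without empty vector 48 h replicate 1, 128 and 132 without GRHL1 48 h replicates 1 and 2, 130 without GRHL1 72 h replicate 1 and 135 without empty vector 72 h replicate 2. At 24 h it was 17 and 24 without empty vector replicates 1 and 2 and 11 and 10 without those of GRHL1, at 48 h 19 and 28, and 28 and 27, and at 72 h 22 and 22 for empty vector and 18 without GRHL1 replicate 1. The change with time was lost without any of 11 arrays, the empty vector call at 48 h without any of 9, and the empty vector count at 72 h moved without any of 12. GRHL1 in empty vector cells, below the detection limit throughout, ranged from -0.65 to 0.26 at 48 h and from -0.58 to 0.34 at 72 h, turning above 0 without 24 h replicate 2 at both times and without 48 h replicate 2 at 48 h (0.25). These are fitted values between readings at background, and their sign does not show a change. Of 1705 settings by named gene and comparison 1359 gave the same call, 341 were weaker and 5 reversed.

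The replicate number as a fixed block gave 0 for empty vector at 72 h and 0 lists at 24 h. Pairs within each time gave 143 in the mean comparison, of which 128 were shared with the main fit. Pairs also gave 19 at 24 h, 33 at 48 h and 0 for the change with time, so the AIF1L call is not made there. Deviations of the 2 transfections with the same number correlated with 0.114, 0.017 and 0.03 at 24, 48 and 72 h. Over all 15 pairs of groups the range was -0.03 to 0.114, so the 24 h value was the highest. These values do not show that the numbers pair the arrays, although the series text speaks of paired samples. The slide as a block was not run because the files name no slide.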

Other observations

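The time lists of GRHL1 plasmid arrays and the look at gene families were chosen only after the result was seen.

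All 4 glutathione S-transferase mu genes that were tested rose in the mean comparison. GSTM1 read 0.93 ± 0.06 (log2 difference, SE, 6 arrays against 6, adjusted p = 3.55e-05), GSTM2 0.96 ± 0.07 (adjusted p = 9.53e-05), GSTM3 0.90 ± 0.07 (adjusted p = 0.000147) and GSTM4 0.70 ± 0.11 (adjusted p = 0.0134). At 24, 48 and 72 h GSTM4 read -0.02, 0.93 and 1.18, and the change with time did not pass for any of the 4 (adjusted p = 0.738 for GSTM4 and 0.52 for GSTM1). These paralogs are close in sequence, and whether 1 transcript is read by several probes was not tested. Beside NDRG1, NDRG2 (0.74 ± 0.12, adjusted p = 0.0158) and NDRG3 (0.38 ± 0.07, adjusted p = 0.0277) rose, while NDRG4 read -0.01 ± 0.06 (adjusted p = 0.986).

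In the GRHL1 plasmid arrays 5 genes were higher and 7 lower at 48 h than at 24 h, and 15 higher and 11 lower at 72 h (limma). By camera 5 lists passed at 48 h and 3 at 72 h, of which none held with an estimated correlation. Immediate early genes had a median of -0.217 at 48 h and -0.187 at 72 h (camera adjusted p = 0.00196 and 0.0026, and adjusted p = 0.185 and 0.296 with an estimated correlation). G1/S genes had medians of 0.088 and 0.071 (camera adjusted p = 0.0124 and 0.0189, and adjusted p = 0.298 and 0.338 with an estimated correlation). Cell cycle inhibitors and p53 targets (median -0.099, camera adjusted p = 0.0121, and adjusted p = 0.185 with an estimated correlation) and the unfolded protein response and ATF4 list (-0.106, camera adjusted p = 0.0378, and adjusted p = 0.685 with an estimated correlation) passed camera at 48 h alone. The cholesterol list at 72 h had -0.351 (camera adjusted p = 3.18e-10, and adjusted p = 0.296 with an estimated correlation). Cholesterol and immediate early genes lay lower in empty vector cells too. Whether these courses differ between the transfections was tested for single genes only, by the change of the GRHL1 difference with time.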
